A study of Mus musculus with 8 samples.

How the data were processed

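Testis cells of C57BL/6 mice at 10 days postpartum were measured by droplet single-cell RNA sequencing in 8 libraries. Of these, 6 came from germ cells enriched by fluorescence-activated sorting and 2 from a suspension of the whole testis, per the labels. The labels give neither the markers of the sort nor the part of Dnmt3a or Dnmt3l that was deleted, and do not say whether a sorted and a whole-testis library share an animal. All libraries used the 10x Genomics 3′ kit, in version 2 for the Dnmt3L pair and in version 3 for the rest, and the protocol states 6000 cells.

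The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger 3.0.2, per the file headers. The submitters' processing notes also name Seurat 3.1.1 and the mm10 build, without giving a role for Seurat. The barcodes had been filtered before deposit, since each has at least 500 UMIs. No normalised values, cell annotation or cluster assignment were deposited, so cell types and stages were rebuilt here. The files list 31053 genes. Of their identifiers 31011 are in GENCODE vM21 (GRCm38), 30481 of them under the same symbol, and 71 of the genes share a symbol with another and were kept apart by identifier. Coordinates were taken from that annotation. The files held no genome sequence, so nothing was computed on promoter sequence or CpG content, and DNA methylation itself was not measured in these samples.

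Each library was its own group, and libraries were grouped by title into 4 pairs of a mutant and its control. The library titled as wild type for Dnmt3L carries a genotype field that reads wild type for Dnmt3A; it was kept as the control of the Dnmt3L knockout because it shares that library's kit version and preparation. The control of the conditional knockout carries a deleted and a floxed allele without Cre, so it is heterozygous for Dnmt3a, whereas the other controls are wild type.

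Cells with at least 500 detected genes and at most 25% mitochondrial UMIs were kept. A limit of 10% had been written down beforehand, but between 21.5% and 75.9% of the barcodes of a library lie above it, so the limit was raised on these quality values alone and the 10% limit was run as an added alternative. Doublet scores were computed with Scrublet at an expected rate of 5%. Its automatic threshold marked almost no cells in most libraries, so the 5% of barcodes with the highest score in each library were removed instead. The kept cells were scaled to 10000 UMIs, log-transformed, centred within each kit version and clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Germ cells were then clustered a second time on their own. Clusters were named from marker lists fixed before the data were examined, by the list with the highest mean log2 level over the mean of all clusters (CPM plus 10) and with at least 3 of its markers found in at least 10% of the cluster's cells; this scoring rule was written after the clusters were seen. Clusters with a median depth under 1/3 of their own libraries' stayed unnamed. A name therefore stands for cells like that type. Undifferentiated spermatogonia were divided into stem-like, progenitor-like and intermediate clusters by a gap of 0.3 between the stem and progenitor scores. Germ cells are the undifferentiated, differentiating, spermatocyte and mixed-stage clusters, the last of these a cluster led by markers of more than a single stage. A germ cell cluster led by Sertoli transcripts was kept out of them, and its share of each library is reported.

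For each library the raw UMIs of a cell class were summed. The 3 Dnmt3A pairs were tested together with edgeR 4.0.16 (R 4.3.3), with filterByExpr, TMM factors, the pair as a block and the quasi-likelihood test, two-sided, and Benjamini-Hochberg adjustment with calls at 0.05. Of the 20 gene lists that had been fixed, those with at least 3 tested members were tested, for all germ cells and for undifferentiated spermatogonia, with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated one, and with fry. A single pair has 1 library per group and no test: its values are CPM (UMIs scaled to the library's summed UMIs with TMM factors) with exact Poisson intervals, shares with exact Clopper-Pearson intervals, both at 95%, and both cover counting error only. Ratios within a pair are log2 ratios of CPM after adding 0.5 to each value. This makes the ratios of weakly expressed genes smaller and can put them outside the exact interval of the UMI ratio, so levels and UMIs are given with them. They were computed for genes with at least 200 UMIs in the pair. A list's median ratio within a pair was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins. Stage shares were compared by log2 odds ratios per pair with an exact sign-flip permutation test over the 3 Dnmt3A pairs.

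Genes named in the text followed a fixed rule. The enzymes Dnmt3a, Dnmt3b, Dnmt3l and Dnmt1 come first. For each edgeR fit the 10 genes with the largest rise and the 10 with the largest fall were taken among those past the threshold, with the same sign in all 3 pairs and at least 10 CPM in a library, leaving out mitochondrial, ribosomal protein and predicted genes. For each pair, and for each somatic class of the whole testis, the 5 highest and 5 lowest ratios were taken, and for each list up to 4 tested members with the largest absolute change. The design, these rules, the lists, the markers and the alternative settings below were fixed before the data were examined. These settings were DESeq2's size factors within edgeR, DESeq2 1.42.0 in place of edgeR, no low-count filter, no pair block, each pair left out, doublets kept, at least 1000 genes with at most 5% mitochondrial UMIs, a clustering resolution of 2 and of 0.5, stage genes left out of the clustering, each pair clustered alone, cells thinned to 4000 UMIs, germ cells defined by Ddx4 and Dazl, equal cells per stage, scaling to total UMIs, and a minimum of 1000 UMIs per pair for correlations. Added after the data were seen were the 10% mitochondrial limit, equal cells per stage for the correlation with the Dnmt3L pair, stem-like clusters alone, and the undifferentiated fit with stage genes left out of the clustering.

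The scripts were tested on simulated counts drawn from the real means and library sizes. In the test of the all-germ-cell comparison on 15706 genes, 93% of the genes changed 2-fold and 100% of those changed 4-fold were recovered, with 12 false calls among 15506 unchanged genes. For undifferentiated spermatogonia on 13758 genes these values were 94% and 100%, with 4 false calls among 13558. For differentiating spermatogonia on 12912 genes all changed genes of both sizes were recovered, with 8 false calls among 12712. In these tests the changed genes were drawn only from genes above a minimum mean count in the smallest library. Recovery therefore does not cover weaker genes. The simulated counts held no difference between pairs or in stage make-up, and fewer genes changed than the real fits called. The false calls therefore do not give the error rate of the real fits. Of the exact intervals of ratios within a pair, 95.2% covered the simulated value over 10593 genes.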

Results

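Single-cell RNA profiles were collected from the testes of mice at 10 days postpartum that lacked the de novo DNA methyltransferase Dnmt3A, its cofactor Dnmt3L, or neither. The 8 libraries form 8 groups of 1 library each and fall into 4 pairs of a mutant and its control. The sorted constitutive pair sets the Dnmt3A knockout against wild type in sorted germ cells, and the whole-testis pair does so without a sort. The conditional pair sets sorted germ cells with Dnmt3A deleted by Prdm1-Cre, which acts in the germ line, against Cre-negative cells that are heterozygous for Dnmt3a. The Dnmt3L pair sets the Dnmt3L knockout against a wild type in sorted germ cells. The wild-type library of the Dnmt3L pair was grouped by its title, because its genotype field names Dnmt3A.

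The files hold 83689698 UMIs in 5785 barcodes for the sorted Dnmt3A knockout and 74337005 in 5524 for its control. The whole-testis libraries hold 74714078 UMIs in 7457 barcodes for the knockout and 73084998 in 6760 for the wild type. The conditional knockout library holds 68673436 UMIs in 4943 barcodes and its control 58643408 in 5005. The Dnmt3L knockout library holds 22230345 UMIs in 3074 barcodes and its control 24176687 in 3034, so this pair is the shallowest. After filtering, 4146 and 3926 cells were kept in the sorted constitutive pair, 4751 and 4397 in the whole-testis pair, 3101 and 2923 in the conditional pair and 2311 and 2438 in the Dnmt3L pair, the mutant first each time. Between 147 and 1673 of a library's cells fell into germ cell clusters, with a median of 11682 to 11748.5 UMIs per germ cell in the Dnmt3L pair and of 25767 to 30988.5 in the others. Each group has a single library, so every comparison within a pair stands without a replicate, and its intervals cover counting error only. The labels do not say that the libraries come from separate animals. The p-values over the 3 Dnmt3A pairs therefore rest on the spread between these pairs. The edgeR fits share their estimate of that spread across genes, so a gene's p does not rest on its own 3 ratios alone.

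The targeted genes were read first, as a check of the labels. Dnmt3a (chromosome 12, 3806007 to 3914443, GRCm38, GENCODE vM21) was lower in germ cells of every Dnmt3A mutant library than in its control. In the sorted constitutive pair its level was 39.5 CPM (37.7 to 41.4) in the knockout and 85.9 (82.7 to 89.2) in the wild type, and in the whole-testis pair 42.1 (36.3 to 48.7) against 81.0 (75.1 to 87.3). In the conditional pair it was 35.5 CPM (33.7 to 37.3) against 52.9 (50.01 to 55.9) in the heterozygous control. In the Dnmt3L pair, where Dnmt3a is intact, it was 74.2 CPM (69.9 to 78.8) against 67.3 (62.7 to 72.2). Across the 3 Dnmt3A pairs Dnmt3a fell by 0.86 on the log2 scale (SE 0.10, adjusted p = 2.76e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Dnmt3l (chromosome 10, 78041947 to 78063622) had 1 UMI in germ cells of the Dnmt3L knockout and 20 in its control, or 0.0685 CPM (0.00173 to 0.382) against 1.72 (1.05 to 2.65). Dnmt3a transcripts thus remained in the knockouts; the deleted part is not given in the sources used here, and 3′ tags outside it would not report the deletion. In Sertoli-like cells Dnmt3a was at 63.2 against 117 CPM in the sorted constitutive pair and 96.0 against 142 in the whole-testis pair, and at 93.8 against 85.5 in the conditional pair. Dnmt1, the maintenance methyltransferase, had log2 ratios between -0.07 and 0.11 in the 4 pairs. Those of Dnmt3b, another de novo enzyme and also a marker used to name differentiating cells, lay between -0.51 and -0.28 in all germ cells. In undifferentiated cells its levels were 66.7 against 61.0, 64.9 against 65.7, 66.6 against 64.7 and, in the Dnmt3L pair, 77.3 (72.4 to 82.5) against 57.7 (50.9 to 65.1) CPM.

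The comparison of stages asks where germ cells without Dnmt3A or Dnmt3L stood along spermatogonial development. In all 4 pairs the mutant library held a larger share of undifferentiated and a smaller share of differentiating spermatogonia, and in the 3 Dnmt3A pairs a smaller share of spermatocytes. These shares add up within a library, so a larger share need not mean more undifferentiated cells. In the unsorted whole testis, undifferentiated cells were 125 of 3879 named cells in the knockout and 72 of 2694 in the wild type. Differentiating cells there numbered 16 against 151, and spermatocytes 1 against 32. Low-depth clusters stayed unnamed and are in no stage. Cluster 1, with the germ cell list highest, held 126 cells against 539 in the sorted constitutive pair, 182 against 646 in the whole testis and 374 against 543 in the conditional pair. Cluster 13, with the spermatocyte list highest, held 5 against 26, 15 against 175 and 23 against 31. Both held 0 cells of the Dnmt3L pair. Undifferentiated cells made up 80.5% (78.5 to 82.4) of 1673 germ cells of the sorted knockout and 37.4% (34.4 to 40.4) of 1052 in its control. In the unsorted whole testis they made up 85.0% (78.2 to 90.4) of 147 against 27.5% (22.2 to 33.3) of 262. In the conditional pair they made up 56.9% (54.3 to 59.6) of 1375 against 29.6% (26.3 to 33.1) of 716, and in the Dnmt3L pair 77.4% (74.99 to 79.6) of 1282 against 36.2% (33.3 to 39.1) of 1089. Differentiating spermatogonia were 16.3% (14.6 to 18.2) against 54.0% (50.9 to 57.0), 10.9% (6.35 to 17.1) against 57.6% (51.4 to 63.7), 31.9% (29.5 to 34.5) against 47.9% (44.2 to 51.6), and 21.5% (19.2 to 23.8) against 60.3% (57.4 to 63.3), in the same order of pairs. Spermatocytes, the cells in meiosis, were 0.956% (0.548 to 1.55) against 5.23% (3.96 to 6.75), 0.680% (0.0172 to 3.73) against 12.2% (8.51 to 16.8), and 8.87% (7.42 to 10.5) against 17.5% (14.7 to 20.4), where the whole-testis knockout value is 1 cell. In the Dnmt3L pair they were 5 cells, 0.390% (0.127 to 0.908), against 12 cells, 1.10% (0.571 to 1.92), and with each pair clustered alone 0 against 0. Within the undifferentiated cells, the progenitor-like cluster held 36 cells (2.67%) of the sorted knockout and 156 (39.7%) of its control, 3 (2.40%) against 21 (29.2%) in the whole testis, 41 (5.24%) against 81 (38.2%) in the conditional pair, and 41 (4.13%) against 129 (32.7%) in the Dnmt3L pair. These progenitor-like shares depend on the clustering: at doubled resolution they were 28.4% against 53.1% in the conditional pair and 27.0% against 63.6% in the Dnmt3L pair, with thinned cells 28.9% against 58.6% in the conditional pair, and under the stricter limits 6 of 12 cells against 15 of 21 in the sorted constitutive pair and 10 of 16 against 18 of 23 in the whole testis. Thinned cells gave 175 of 1377 against 189 of 424 in the sorted constitutive pair and 129 of 957 against 242 of 433 in the Dnmt3L pair. The added limit of 10% mitochondrial UMIs gave 2 of 147 against 3 of 44 in the conditional pair.

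Over the 3 Dnmt3A pairs the mean log2 odds ratio was 2.77 (SD 1.11, n = 3) for undifferentiated spermatogonia, -2.33 (SD 1.25) for differentiating spermatogonia and -2.46 (SD 1.33) for spermatocytes. Each had p = 0.25 in the two-sided exact sign-flip permutation test, the smallest p that 3 pairs allow. With the stage genes left out of the clustering the means were 3.16, -2.70 and -2.03, and under the stricter limits on cells, which left no spermatocytes, 1.53 and -0.92. The germ cell cluster led by Sertoli transcripts, which is in none of these stages, held 1.19% of the named cells of the sorted knockout and 3.65% of its control, 0.103% and 1.52% in the whole testis, 4.29% and 8.03% in the conditional pair, and 1.15% and 9.40% in the Dnmt3L pair.

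**Figure D1:**
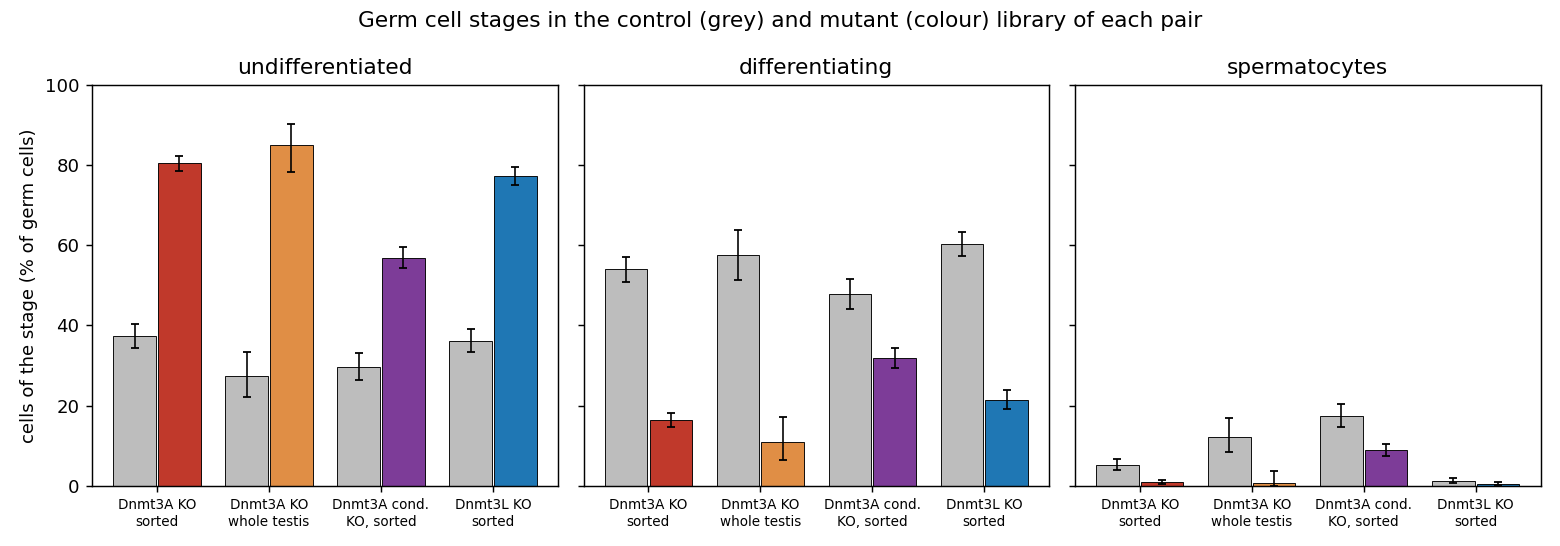
Share of germ cells in each stage, in percent, for the mutant and the control library of each of the 4 pairs; bars give the share and whiskers the exact 95% binomial interval. Undifferentiated spermatogonia take 56.9% to 85.0% of germ cells in the mutants and 27.5% to 37.4% in the controls.

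The next comparison asks which transcripts changed in germ cells without Dnmt3A, over the 3 Dnmt3A pairs. The largest rises were those of Igdcc3, a cell surface protein of the immunoglobulin superfamily, Cd2, an adhesion molecule best known from T cells, Apom, an apolipoprotein, and Rhox5, a homeobox gene of the X chromosome. Igdcc3 (chromosome 9, 65141189 to 65185872) rose by 4.69 on the log2 scale (SE 0.22, adjusted p = 9.36e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 0.864 to 30.1 CPM in the sorted constitutive pair, 0.704 to 29.0 in the whole testis and 1.13 to 16.3 in the conditional pair. Rhox5 (chromosome X, 37804842 to 37808876) rose by 3.97 (SE 0.28, adjusted p = 9.01e-07, same test), with 131 against 4.51, 114 against 4.57 and 75.6 against 10.6 CPM. Cd2 rose by 4.62 (SE 0.25) and Apom by 4.45 (SE 0.26). Ggt5, Glmp, Cdh5, Krt18, Trim46 and Ltb rose by 2.84 to 3.55. Among the falls, the transcription elongation factor gene Tcea3 (chromosome 4, 136247729 to 136274898) led with -3.00 (SE 0.23, adjusted p = 1.47e-06, same test). It was followed by Ccdc113, by the transcription factor genes Onecut2 (-2.80), Lef1 (-2.65, a mediator of Wnt signalling) and Klf5 (-2.49), and by Npnt, Myh3, Plk5, Prtg and Lmo1, between -2.34 and -2.04. The rule that names these 20 genes asks for the same sign in all 3 pairs.

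Of 15706 genes tested in all germ cells, 7272 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3589 higher and 3683 lower. Because the stage shares differ between the libraries of each pair, the same number of cells per stage was drawn from both, and 3511 genes then passed. Without the pair block 2633 genes passed, without the sorted constitutive pair 3748, and under the stricter limits on cells 756 of 6846 tested.

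Of 13 markers of stem spermatogonia 12 rose and none fell in germ cells without Dnmt3A (adjusted p 3.59e-17 in camera with a preset correlation; adjusted p = 0.382 with an estimated correlation), where undifferentiated cells take a larger share of every mutant library. Among them were Pax7 (2.83), Id4 (2.17, an inhibitor of differentiation), Tspan8 (1.87) and Lhx1 (1.87), of which the last 3 also served to name clusters. The GDNF, FGF and KIT signalling list, which shares Gfra1, Ret, Etv5, Lhx1 and Bcl6b with the stem list, had 10 of 13 genes higher and 3 lower, with Spry4 at 1.89, Spry2 at 1.63, both feedback inhibitors of the pathway, Lhx1 at 1.87 and Kit at -1.85. Of the 12 markers of differentiating spermatogonia 11 fell and 1, the cyclin gene Ccnd2, rose; the falls included Prss50 (-2.01), Kit (-1.85), Dmrtb1 (-1.46) and Stra8 (-1.45, the gene induced by retinoic acid before meiosis). Progenitor markers had 6 of 12 lower, with Neurog3 at -1.88, Sox3 at -1.37 and Utf1 at -1.09, and 1 higher, Cdh1 at 1.24. Of 22 meiotic prophase genes 13 fell and 2 rose, or 14 and 2 adjusted over the list alone, with Meiob, Majin, Prdm9 and Meioc between -0.99 and -0.88. These lists passed camera with a preset correlation, with adjusted p of 3.59e-17 for stem, 4.36e-08 for GDNF, 5.95e-06 for differentiating, 0.0171 for progenitor and 0.0144 for meiotic genes. With an estimated correlation none did, though with 6 libraries that form can hardly pass any list. Camera gave adjusted p = 0.382 with an estimated correlation for the first 3, 0.398 for progenitor and 0.428 for meiotic genes. Fry, whose PValue asks whether a set's genes move on balance in 1 direction and whose PValue.Mixed asks whether they change in either, gave adjusted p of 0.0264 for stem and 0.0168 for GDNF genes, but 0.0755 for progenitor, 0.0812 for differentiating and 0.0755 for meiotic genes; the mixed values of these 5 lists lay between 0.0159 and 0.0424. Without the sorted constitutive pair the progenitor list had an adjusted p of 0.0978 in camera.

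In the Rhox cluster, homeobox genes in tandem on the X chromosome, 12 of 22 tested genes rose and 1, Rhox13, fell, or 12 and 2 adjusted over the list alone; Rhox5 (3.97), Rhox6 (1.83), Rhox4g (1.73) and Rhox3h (1.68) led, and reads of the near-identical Rhox2, Rhox3 and Rhox4 copies are uncertain. Of 12 immediate early and heat shock genes 8 rose and 1 fell, with Ier3 at 2.28, Ier2 at 0.97, Junb at 0.95 and Hspa1a at -0.79. In the piRNA pathway, which silences transposons in germ cells, 8 of 18 rose and 3 fell, or 8 and 4 adjusted over the list alone, with Gtsf1 at 1.25, Piwil4 at 0.91, Morc1 at 0.80 and Pld6 at -0.77. Of 9 genes of DNA methylation and the TET pathway none rose and 5 fell, namely Tet3 (-1.42), Dnmt3l (-1.09), Dnmt3a, Tdg (-0.42) and Dnmt3b (-0.39). Dnmt3l had few UMIs, 29 against 56 in the sorted constitutive pair and 52 against 62 in the conditional pair. In the whole testis it was at 0.906 against 0.821 CPM, from 4 and 7 UMIs. In undifferentiated cells Dnmt3b did not pass, at 0.04 (adjusted p 0.698, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Camera with a preset correlation gave adjusted p of 0.000346 for Rhox, 0.00460 for immediate early, 0.0283 for piRNA and 0.0326 for DNA methylation genes, and for each of these lists adjusted p = 0.382 with an estimated correlation. The piRNA list lost its camera call without the sorted constitutive pair (adjusted p 0.0906), without the conditional pair (0.0752) and without the pair block (0.0672).

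Other lists did not pass camera in germ cells. Germline genes that promoter methylation silences in other tissues had 7 of 16 higher and 5 lower, led by Rpl10l (0.69), Stk31 (0.68), Asz1 (0.62) and Dpep3 (-0.55), with an adjusted p of 0.118 in camera and 0.0264 in fry. Of 22 imprinted genes, which carry methylation from a single parent, 10 rose and 8 fell (11 and 8 adjusted over the list alone), with Mirg at 1.43, Mest at 1.37, Sgce at -1.26 and Ndn at 1.24 (camera adjusted p 0.267). Interferon response genes had 4 of 8 higher and 1 lower, or 4 and 2 adjusted over the list alone, with Isg15 at 2.70, Usp18 at -1.94, Ifi27 at 1.57 and Bst2 at 0.57 (camera 0.0610, without the whole-testis pair 0.0368; fry 0.0168). Cell division genes had 1 of 18 higher and 8 lower, with Plk1 at -0.53, Birc5 at -0.50, Aurkb at -0.40 and Aurka at -0.30 (camera 0.0744, without the whole-testis pair 0.0170). Of 11 p53 response genes 3 rose and 5 fell, with Pmaip1 at 1.15, Zmat3 at 1.14, Phlda3 at -1.01 and Ccng1 at -0.72; the median was 0.02 and the mean -0.01, so they differ in sign (camera 0.731). Of 13 glycolysis genes 4 rose and 5 fell, with Pfkp at 0.67, Pkm at 0.48, Hk1 at -0.42 and Hk2 at -0.40; here the median was -0.02, and the mean of 0.01 and the test pointed up (camera 0.9504).

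Markers used here for other cell types also moved in germ cells. Of 6 endothelial markers 4 rose and none fell, with Cdh5 at 3.25, Vwf at 2.65, Kdr at 1.70 and Flt1 at 1.63 (camera adjusted p 1.19e-05; adjusted p = 0.382 with an estimated correlation). The summed level of these markers in germ cells was 92.4 against 50.1 CPM in the sorted constitutive pair, 100.4 against 55.2 in the whole testis, 75.4 against 44.4 in the conditional pair and 117.4 against 66.1 in the Dnmt3L pair, and the macrophage marker Cd68 rose by 2.18. The sorted libraries held at most 1 endothelial cell each, while germ cells of the sorted knockout carried 4173 UMIs of the endothelial markers. Of 10 Sertoli markers 2 rose and 6 fell, or 2 and 7 adjusted over the list alone, with Wt1 at -0.97, Amhr2 at -0.72, Amh at 0.56 and Sox9 at -0.55 (camera 0.0689, without the whole-testis pair 0.00413). Of 11 peritubular and mesenchymal markers 1 rose and 4 fell, with Cnn1 at -1.87, Lum at 1.31, Des at -1.05 and Col1a1 at -0.83 (camera 0.480). In the whole-testis pair the sums were higher in the knockout, with Sertoli markers at 831 against 785 CPM and peritubular and mesenchymal markers at 117 against 92.0. The Leydig and macrophage lists had fewer than 3 tested genes; summed Leydig markers lay at 6.13 against 7.91 CPM and macrophage markers at 6.07 against 0.965 in the sorted constitutive pair.

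Undifferentiated spermatogonia were compared on their own to ask what changed within a single stage. Igdcc3 rose by 4.72 on the log2 scale (SE 0.20, adjusted p = 1.15e-14, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Apom by 4.66 (SE 0.30) and Cd2 by 4.37 (SE 0.22). Rhox5 rose by 3.62 (SE 0.15, adjusted p = 1.14e-14, same test), with 156 against 7.70 CPM in the sorted constitutive pair, 128 against 9.08 in the whole testis and 113 against 15.4 in the conditional pair. Ptprcap, the olfactory receptor gene Olfr12, Glmp, the apolipoprotein gene Apoc1, Ggt5 and Glrx, a glutaredoxin, rose by 2.87 to 4.26. Rspo1 (chromosome 4, 124986430 to 125009099), a secreted amplifier of Wnt signalling, had the largest fall, -4.71 (SE 0.29, adjusted p = 5.47e-12, same test). The developmental transcription factor genes Onecut2 (-3.66), Barhl2 (-3.51), Zic1 (-3.37), Lef1 (-3.11) and Neurog3 (-2.92) fell, as did Sntg2 (-3.45), Ccdc113 (-2.97), the Wnt antagonist gene Sfrp2 (-2.84) and Rin2 (-2.82). Different clusters held most of this class in the 2 genotypes: knockout cells lay mainly in clusters 3, 4, 5, 10 and 11 and control cells in clusters 0, 9 and 15. Igdcc3, Rhox5 and Lhx1 are among the leading genes of clusters 3, 10 or 11, Onecut2, Rin2 and Neurog3 of the progenitor-like cluster 0, Sfrp2 of cluster 9 and Barhl2 of cluster 15, so their values here partly define the clusters; the comparison of all germ cells does not use these divisions.

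Of 13758 genes tested in undifferentiated spermatogonia 5297 passed, 2700 higher and 2597 lower. DESeq2 passed 2758, edgeR without the pair block 1310 and without the sorted constitutive pair 2431, and the stricter limits on cells left 15 of 1254. The alternatives chosen after the data were seen gave 1841 calls with at most 10% mitochondrial UMIs and 1495 with stem-like clusters alone. With stage genes left out of the clustering there were 5266.

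**Figure D2:**
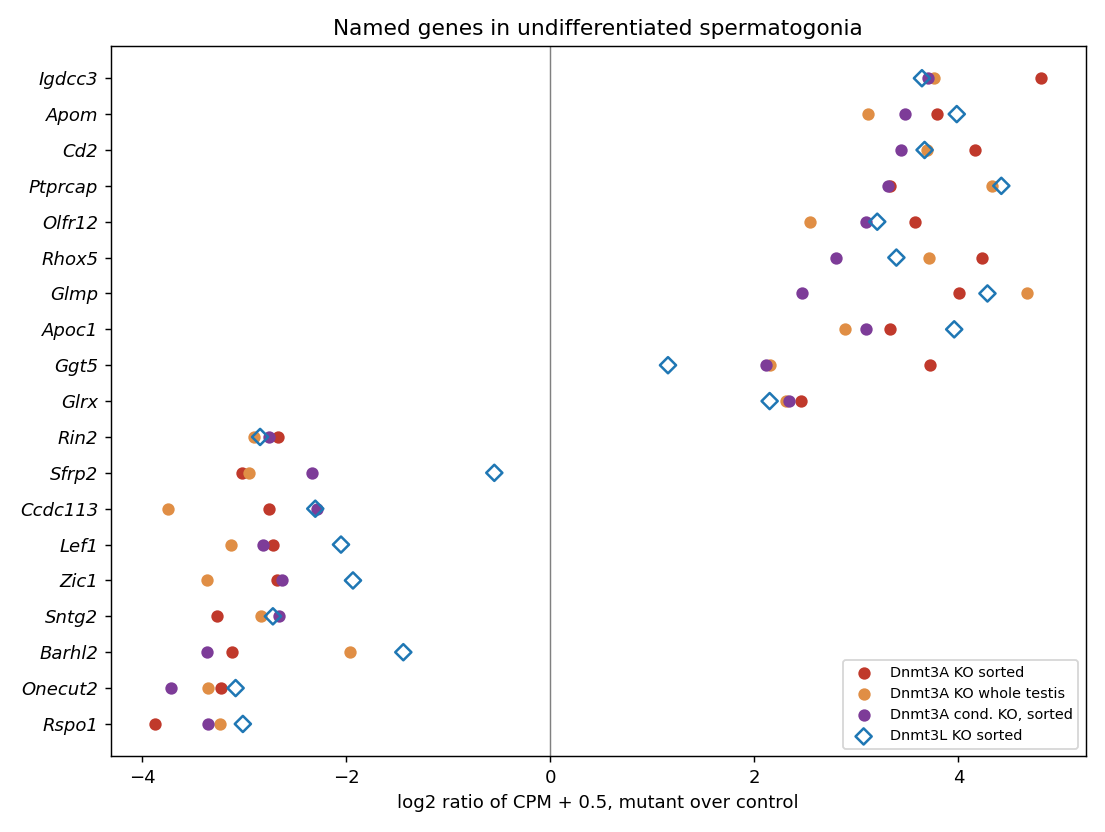
Log2 ratios of CPM plus 0.5, mutant over control, in undifferentiated spermatogonia for the 10 genes with the largest rise and the 10 with the largest fall over the Dnmt3A pairs, without Neurog3, which served to name clusters; each point is 1 of the 4 pairs. All points of a gene lie on the same side of 0, the Dnmt3L pair included.

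Within this stage 11 of 12 progenitor markers fell, led by Neurog3, Sox3 (-2.19), Ddit4 (-1.80) and Upp1 (-1.78), and Cdh1 rose by 0.66. All of these markers also served to name clusters, as did Kit, Dmrtb1, Sohlh1, Id4, Tspan8, Nanos2 and Bcl6b below. The progenitor-like cluster held 36 of 1347 undifferentiated cells of the sorted knockout and 156 of 393 of its control. The fall of the progenitor markers therefore cannot be parted from the make-up of the class. Of 12 differentiation markers 7 fell and 2 rose, or 8 and 2 adjusted over the list alone, with Kit at -2.04, Dmrtb1 at -1.77, Sohlh1 at -0.78 and Dmrt1 at -0.68. Stem markers had 8 of 13 higher and 2 lower: Pax7 (1.78), Id4 (1.20), Tspan8 (0.89) and Nanos2 (0.81) rose, and Pou5f1 (-0.48) and Bcl6b (-0.46) fell. Of 17 Rhox genes 11 rose and 1, Rhox8, fell, or 13 and 1 adjusted over the list alone, with Rhox6 at 1.95 and Rhox9 at 1.52. Endothelial markers rose here too, 5 of 6, with Cdh5 at 2.79 and Vwf at 2.42, while 7 of 10 Sertoli markers fell and 2 rose, with Wt1 at -1.19, and 3 of 4 tested peritubular markers fell, with Col1a1 at -1.50. The whole-testis pair went the other way, with summed Sertoli markers at 836 against 700.1 CPM and peritubular markers at 128 against 89.99 in its undifferentiated cells. The macrophage marker Cd68 rose by 1.98. Camera with a preset correlation gave adjusted p of 3.68e-19 for progenitor, 4.58e-05 for differentiating and 8.64e-06 for each of the stem, Rhox and endothelial lists, all with adjusted p = 0.349 with an estimated correlation. With stem-like clusters alone, an alternative chosen after the data were seen, the stem list pointed down with an adjusted p of 0.0705 in camera. The Sertoli and peritubular lists had camera values of 0.0912 and 0.0919, and 0.00239 and 0.0139 without the whole-testis pair.

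Glycolysis genes had none of 13 higher and 7 lower in undifferentiated spermatogonia, with the glucose transporter gene Slc2a1 at -1.01, Hk1 at -0.93 and Eno1 at -0.77 (camera adjusted p 0.00788; adjusted p = 0.523 with an estimated correlation; fry 0.0922; camera without the pair block 0.0714). Immediate early genes had 5 of 10 higher and 2 lower, or 7 and 2 adjusted over the list alone, with Hspa1a at -1.74, Ier3 at 1.38, Junb at 1.13 and Jun at 0.84 (camera 0.0491; adjusted p = 0.361 with an estimated correlation; without the sorted constitutive pair 0.0985, without the whole-testis pair 0.135, without the block 0.161; fry 0.0511). Of 9 DNA methylation genes Dnmt3l (-1.92), Tet3 (-1.87) and Dnmt3a (-0.93), the targeted gene itself, fell and Dnmt1 rose by 0.31. Dnmt3l was weakly expressed, at 0.683 against 3.73 CPM in the sorted constitutive pair and 1.86 against 6.03 in the conditional pair. In the whole testis it was the other way, at 1.09 against 0.826, from 4 and 2 UMIs. The list's median was 0.04 while its mean of -0.45 and camera pointed down (0.0498, and adjusted p = 0.361 with an estimated correlation). Camera gave 0.0513 without the sorted constitutive pair, 0.611 without the conditional pair and 0.0822 without the block. The remaining lists did not pass camera: p53 response (7 of 10 higher, 2 lower, 0.205), interferon (4 of 7 and 2, 0.243), GDNF signalling (7 of 13 and 4, 0.157), meiotic (6 of 22 and 1, 0.0912; 0.0414 without the conditional pair), methylation-silenced germline (6 of 16 and 3, 0.260), piRNA (6 of 18 and 6, 0.797), imprinted (6 of 22 and 5, 0.797) and cell division genes (5 of 18 and 4, 0.931). Fry passed the p53, GDNF and piRNA lists, with adjusted p of 0.0485, 0.0485 and 0.0158. Zmat3 (0.56), Isg15 (1.77), Spry2 (1.24), Rad51ap2 (1.01), Gtsf1 (0.78), Sgce (-2.10), Dlk1 (-1.42) and Peg10 (-1.35) were among their largest changes. The median and mean of the piRNA and imprinted lists differ in sign, and the cell division list had a median of -0.05 while its test pointed up.

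**Figure D3:**
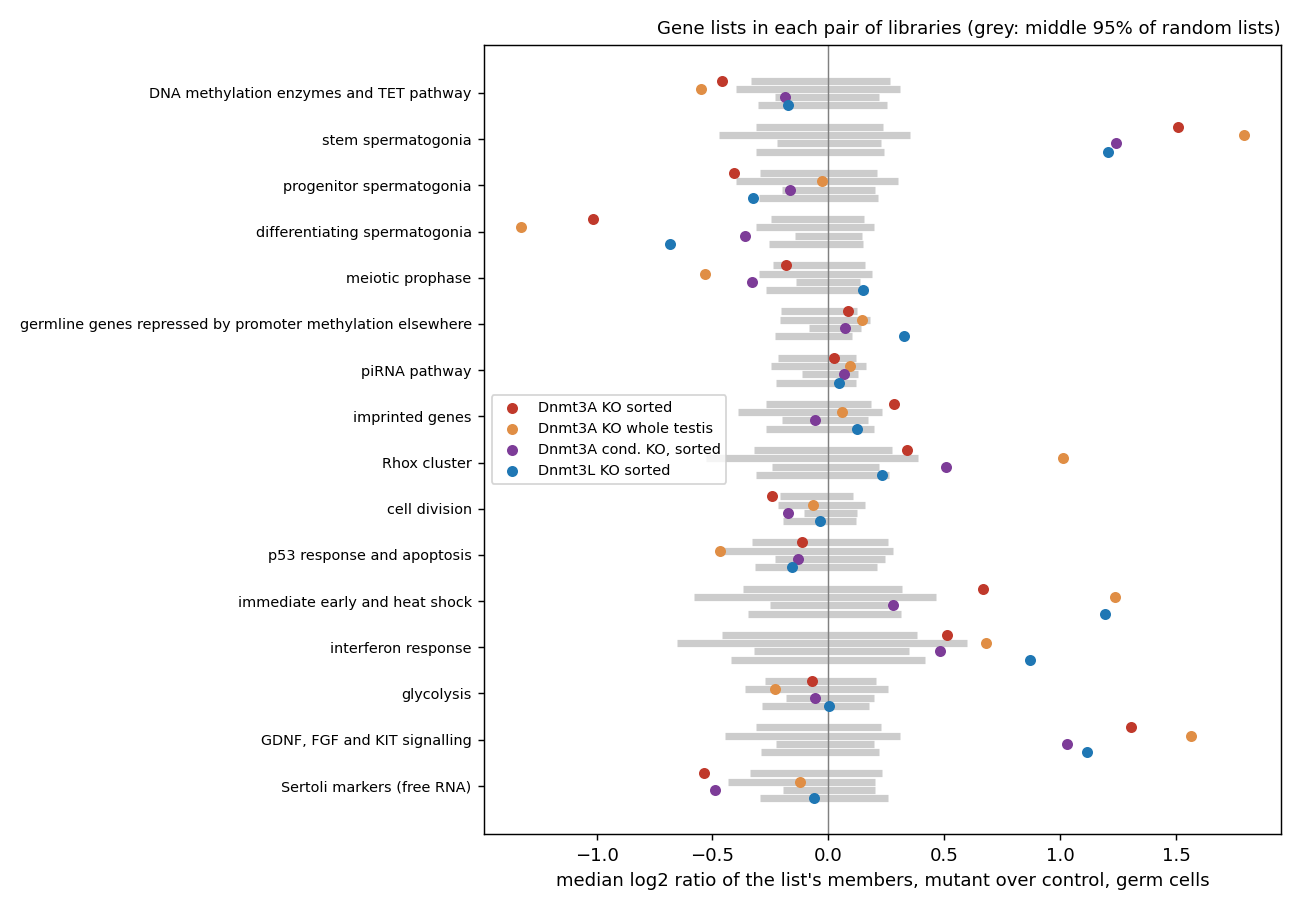
Median log2 ratio of the members of each gene list in all germ cells, mutant over control, for each of the 4 pairs; grey bars span the middle 95% of random lists matched on mean expression. The stem and GDNF lists lie to the right of their bars in all 4 pairs and the differentiating list to the left.

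Differentiating spermatogonia were compared to ask whether cells that had reached that stage still differed. Rhox5 rose by 3.01 (SE 0.29, adjusted p = 3.76e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Glmp by 2.65 and Pet2 by 1.98 (SE 0.07, adjusted p = 2.46e-14, same test). BC028528, Tsga8, Fndc3c1, Hist2h2ac, the chaperone gene Dnaja4, the cancer-testis antigen gene Magea2 and Penk, which encodes proenkephalin, rose by 1.76 to 2.33. Bcl11b (chromosome 12, 107910403 to 108003602), a zinc finger transcription factor gene, fell by 4.14 (SE 0.33, adjusted p = 2.83e-08, same test). Ccdc113, Myh3, Lef1, Taok3, Clic6, Lrrc2, Efcc1, Tcea3 and Cacng4 fell by 1.77 to 3.34. Of 12912 genes 2636 passed, 1347 higher and 1289 lower. DESeq2 passed 468, edgeR without the pair block 31, without the sorted constitutive pair 580, without the conditional pair 484, the stricter limits on cells 448 of 6053, and the added limit of 10% mitochondrial UMIs 1445. The knockout whole testis held 16 of these cells. Efcc1 and Tcea3 missed the threshold with DESeq2 (adjusted p 0.192 and 0.0996), and Hist2h2ac, Penk and Efcc1 in edgeR without the sorted constitutive pair (0.0681, 0.0528 and 0.892). With at most 10% mitochondrial UMIs edgeR gave Taok3 0.0346 (adjusted p 0.946) and Cacng4 an adjusted p of 0.0509, and without the pair block 9 of the 20 genes missed, BC028528, Tsga8, Hist2h2ac, Penk, Taok3, Lrrc2, Efcc1, Tcea3 and Cacng4.

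Within single pairs, levels in all germ cells were set side by side to show what each mutant library held, ranked among genes with at least 200 UMIs in the pair. Rhox5 had the highest ratio of the sorted constitutive pair, with 5879 against 141 UMIs, followed by Igdcc3, Cd2, Glmp and Apom, and Bcl11b had the lowest, with 11 against 203 UMIs, followed by Tcea3, Klf5, Ccdc113 and Mirt1. With equal cells per stage Tcea3 was at -1.58 against -3.02 and Mirt1 at -1.32 against -2.49, and in cells defined by Ddx4 and Dazl Glmp was at 1.77 against 3.63. In the whole testis Rhox5 again led, with 505 against 39 UMIs, followed by Matn4, Erbb3, Optn and Id4. Below 200 UMIs Igdcc3 (128 against 6) had a higher ratio than Rhox5, and Tcea3 (1 against 194) a lower ratio than the lowest named here. The lowest there were Dmrtb1 (18 against 507 UMIs), Tbx1, Prss50, Ly6k and Lmo1. In undifferentiated cells alone the log2 ratios of Tbx1, Prss50 and Ly6k were -0.02, -0.55 and -0.79, with intervals that hold 0, against -3.55, -3.55 and -3.34, and those of Dmrtb1, Matn4, Optn and Id4 were -1.94, 1.76, 1.64 and 1.22 against -3.71, 3.01, 2.83 and 2.62. With equal cells per stage Tbx1, Prss50, Ly6k and Dmrtb1 were at -2.13, -1.24, -1.07 and -1.96, and Matn4, Optn and Id4 at 1.69, 1.64 and 1.39. In cells defined by Ddx4 and Dazl the ratios of Rhox5, Erbb3 and Optn in this pair were 1.55, 1.28 and 1.17 against 4.50, 2.88 and 2.83. In the conditional pair Cd2 (470 against 15 UMIs), Igdcc3, Olfr12, Ifitm3 and Ptprcap were highest and Onecut2 (152 against 763), Lef1, Barhl2, Ccdc113 and Tcea3 lowest. In the Dnmt3L pair Clec2g, a C-type lectin gene, led with 43.9 CPM (40.5 to 47.4) against 0.258 (0.0531 to 0.753), from 640 and 3 UMIs, followed by the interferon-induced Ifitm3 (655 against 4 UMIs), Apoh, Tmem40 and Sfi1. Clec2g, Ifitm3 and Sfi1 are among the leading genes of cluster 13, which holds 522 cells of this knockout and 10 of its control. Pla2g1b (57 against 372 UMIs), Lmo1, Tbx1, Tcea3 and Ccdc113 were lowest there. In undifferentiated cells alone Tbx1 was at -0.48 (-1.40 to 0.34) against -2.51, and with equal cells per stage Lmo1 was at -1.56 against -2.59 and Tcea3 at -1.36 against -2.48.

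The median log2 ratios of the stem list were 1.51, 1.79, 1.24 and 1.21 in the sorted constitutive, whole-testis, conditional and Dnmt3L pairs, each at percentile 100 among 10000 random lists matched on mean expression. Those of the differentiating list were -1.02, -1.33, -0.36 and -0.68, each at percentile 0. Most members of both lists served to name clusters, and undifferentiated cells take a larger share of every mutant library. These percentiles are therefore not separate from the stage shares. The Rhox list had medians of 0.34, 1.01, 0.51 and 0.23 at percentiles 98.9, 99.98, 99.98 and 95.9; in undifferentiated cells alone the whole-testis value was 0.38 and with equal cells per stage 0.49. The meiotic list had -0.18, -0.53, -0.33 and 0.15 at percentiles 7.95, 0.01, 0 and 96.5, and methylation-silenced germline genes 0.08, 0.14, 0.07 and 0.33 at 93.6, 94.9, 82.2 and 100.

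The Dnmt3L pair was set beside the Dnmt3A pairs to ask whether loss of the cofactor went with the same transcripts as loss of the enzyme. The 3 comparisons above name 45 distinct genes, some in more than 1 set, and each had the same sign in the Dnmt3L pair as over the Dnmt3A pairs. Among the 10 genes that rose most in all germ cells such as Rhox5, the median log2 ratio of CPM plus 0.5 was 3.14 for the mean of the Dnmt3A pairs and 3.64 in the Dnmt3L pair, and among the 10 that fell most, such as Tcea3, -2.38 and -2.29. In undifferentiated cells these medians were 3.54 and 3.66 for the rises and -2.87 and -2.51 for the falls, with Sfrp2 at -2.74 and -0.55. In differentiating cells they were 1.90 and 1.54, and -2.07 and -1.88. The interval of the Dnmt3L ratio excluded 0 for all 31 distinct genes of the first 2 sets, and for 7 rises and 9 falls of the third. Across 7345 genes with at least 200 UMIs in every pair, the Pearson correlation of log2 ratios was 0.836 to 0.907 between the Dnmt3A pairs, 0.755 to 0.830 between the Dnmt3L pair and each of them, and 0.812 (Spearman 0.754) with their mean. Genes are not independent replicates, the pairs have separate controls and the Dnmt3L pair another kit version, so whether the mutants differ was not tested. With equal cells per stage, chosen after the data were seen, the correlation with the mean was 0.719 (Spearman 0.644). The Dnmt3A pairs then had 0.637 to 0.792 between them, and the Dnmt3L pair 0.620 to 0.715 with each. Across 4866 genes in undifferentiated cells alone the correlation with the mean was 0.747. Between the Dnmt3A pairs it was 0.715 to 0.842 there, and between the Dnmt3L pair and each of them 0.658 to 0.742. In these cells 498 genes were higher and 383 lower in all 4 pairs by intervals that exclude 0.

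**Figure D4:**
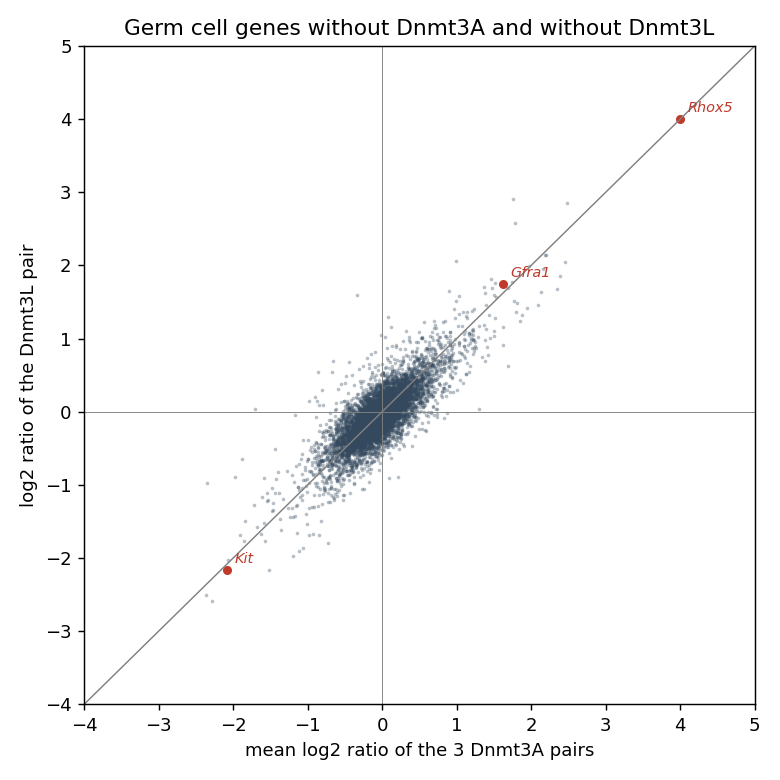
Log2 ratio of each of 7345 genes in all germ cells, the mean of the 3 Dnmt3A pairs on the x axis and the Dnmt3L pair on the y axis, with the line of equal values. The Pearson correlation across genes is 0.812, and Rhox5 and Gfra1 lie above 0 and Kit below 0 on both axes.

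The whole-testis libraries, the only ones without a sort, were compared for their make-up. Germ cells were 147 of 3879 named cells of the knockout, 3.79% (3.21 to 4.44), and 262 of 2694 of the wild type, 9.73% (8.63 to 10.9). Sertoli-like cells, which nurse the germ cells, were 28.6% (27.2 to 30.1) and 31.3% (29.5 to 33.0). Interstitial mesenchyme was 35.3% (33.8 to 36.9) and 29.4% (27.7 to 31.2), and peritubular myoid cells, which line the tubules, 22.8% (21.5 to 24.2) and 16.3% (14.9 to 17.7). Leydig-like cells, the source of androgens, were 5.88% and 6.90%, macrophages 1.60% and 2.41%, endothelial cells 0.954% and 1.30%, and pericytes or vascular smooth muscle 0.773% and 1.11%. Of all kept cells 18.4% of the knockout and 38.7% of the wild type stayed unnamed, which limits these shares. The unnamed cells include the germ-like cluster 1, with 182 cells of the knockout and 646 of the wild type. They also include the spermatocyte-like cluster 13, with 15 and 175, so the germ cell counts leave these out. Under the stricter limits on cells germ cells were 1.83% of the knockout and 16.4% of the wild type, Sertoli-like cells 5.50% and 13.98%, mesenchyme 49.1% and 44.2%, peritubular cells 37.4% and 16.2% and Leydig-like cells 1.83% and 1.32%, and with the added limit of 10% mitochondrial UMIs Sertoli-like cells were 10.02% and 11.1% and mesenchyme 47.9% and 43.7%.

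The somatic cells of the same libraries were compared because the constitutive knockout lacks Dnmt3A there too. In Sertoli-like cells the ephrin receptor gene Epha5 was at 29.2 CPM (27.3 to 31.3) in the knockout and 1.87 (1.39 to 2.47) in the wild type, and Gdf15, a stress-responsive growth factor gene, at 18.0 (16.4 to 19.6) and 1.01 (0.667 to 1.47). AI467606 (221 against 2 UMIs), Omp and Adamts16 completed the highest 5. The lowest 5 were transcripts of germ cells, Stra8 at 2.46 CPM (1.92 to 3.104) against 51.6 (49.0 to 54.4), Ly6k, Tex101, Crabp1 and Prss50. Of 10584 genes 496 (4.69%) had a ratio beyond 1 on the log2 scale, 225 higher and 271 lower. The Sertoli-like cells of these 2 libraries lie in different clusters: 67.7% of those of the knockout are in cluster 15 and 23.9% in cluster 9, and 42.8% of those of the wild type in cluster 12 and 45.6% in cluster 14. Those of the sorted constitutive pair share clusters 12 and 14, with 28.4% and 55.1% in the knockout and 43.1% and 46.0% in the wild type. The median log2 ratio of the cell division list was 0.62 in Sertoli-like cells of the whole testis, 0.31 in the sorted constitutive pair, 0.33 in the conditional pair and 0.39 in the Dnmt3L pair, each at percentile 100, so also where these cells keep Dnmt3a. Cluster 9, led by Ube2c, Prc1 and Cdk1, holds 6.89% of the wild-type cells. In peritubular myoid cells Igfbp5, which binds insulin-like growth factors, was at 241 against 31.5 CPM. Markers of other cell types differed as well: Sertoli markers had a median log2 ratio of 0.71 in peritubular cells, whose own markers were at -0.35, and of 0.41 in mesenchyme, and Leydig and peritubular markers of 1.10 and 0.62 in Sertoli-like cells. In Leydig-like cells the apolipoprotein gene Apoc1 was at 318 against 72.0 CPM and the stress-induced Gadd45b at 21.2 against 309.7, with Junb at 73.5 against 669. The immediate early and heat shock list, which also responds to the dissociation of tissue, had a median log2 ratio of -0.62 in Leydig-like cells and -0.42 in mesenchyme, each at percentile 0, but 0.39 in Sertoli-like cells and 0.47 in macrophages.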

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

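Of the tests in this part, only the limits for Sertoli RNA among the genes with the largest rise were set before their result was seen; all the others were chosen after it, as were the limits that go with them.

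The median ratio of meiotic prophase genes had opposite signs in the Dnmt3A pairs and the Dnmt3L pair, a difference between groups that was not tested. Their median log2 ratio in germ cells was -0.18 in the sorted constitutive pair, -0.53 in the whole-testis pair, -0.33 in the conditional pair and 0.15 in the Dnmt3L pair. The first and the last of these, at percentiles 7.95 and 96.5, lie within the middle 95% of random lists. In undifferentiated cells alone the medians were 0.22, 0.26, 0.09 and 0.45, above 0 in every pair, so the opposite signs are not seen within that stage.

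In undifferentiated spermatogonia 24 genes were higher in all 3 Dnmt3A pairs and lower in the Dnmt3L pair, by intervals that exclude 0, and 3 genes, Hspd1, Cpxm1 and Stra8, the other way. This difference between groups was not tested either, the intervals cover counting error only, and 0 genes were opposite past 1 on the log2 scale. The 24 include the ribosomal protein genes Rpl12, Rpl21, Rps20 and Rps29, and Hmgcs1, Cep164 and Map3k4, named after their values were seen. The ratios are small: Cep164 was at 0.57, 0.46, 0.45 and -0.27, and Rps29 at 0.29, 0.26, 0.15 and -0.04, with the Dnmt3L pair last. The Dnmt3L pair was made with another kit version, which these libraries cannot part from the mutation.

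Sertoli-like cells are also present in the libraries sorted for germ cells, which none of the comparisons uses for these genes, and the genes highest in the knockout whole testis were read there. In the sorted constitutive pair the log2 ratios were 3.23 for Epha5, 3.09 for AI467606, 2.55 for Omp, 1.56 for Gdf15 and 1.48 for Adamts16. Epha5 was at 0.96 in the conditional pair, and at 1.29 in the Dnmt3L pair, where Gdf15 was at 2.06. The others had intervals that hold 0: in the conditional pair Gdf15 at 0.47, Adamts16 at 0.40, Omp at 0.25 and AI467606 at -0.13, and in the Dnmt3L pair Adamts16 at 0.44 and Omp at 0.29, while AI467606 had 0 UMIs in both libraries.

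The changed genes of germ cells were weighed against chance, stage make-up and stray RNA. Only the real division of the 6 Dnmt3A libraries gave as many calls, 1 of 10 divisions in each comparison, with 7272, 5297 and 2636 genes and at most 0 in any other, but 10 are too few for a share under 0.05, and only 4 of them part every pair. With equal cells per stage the median gene kept 0.546 of its log2 change among genes called higher and 0.491 among those called lower, between the limits of 0.25 and 0.75. This does not tell how much of these changes differing stage shares account for. The draw evened only the broad stages and left the stem-like and progenitor-like shares within undifferentiated cells uneven. Of the genes called, 1555 of 3420 higher and 1262 of 3592 lower ones still passed. All 10 genes with the largest rise, Igdcc3 and Rhox5 among them, lay above the level that Sertoli markers predict in all 3 knockout libraries, which argues against free Sertoli RNA as their source.

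The Sertoli-like cells of the knockout whole testis were weighed between germ cell RNA, loss of Dnmt3A in Sertoli cells, and the animal or its maturity. Past 1 on the log2 scale lay 496 genes, of which a share of 0.492 (0.447 to 0.537) were higher in wild-type germ cells. Among all 10584 genes the share was 0.510. This test pools 0.561 of the lower with 0.409 of the higher genes. Fewer germ cells would lower germ cell RNA, but transcripts that rose in knockout germ cells could go the other way. The test therefore does not settle whether free germ cell RNA takes part. Of the genes higher in the knockout and not higher in germ cells, 91.7% were also higher in the sorted constitutive pair and 68.2% in the conditional pair, where Sertoli cells keep Dnmt3a; of the lower genes 94.1% and 80.7% were lower, and in the Dnmt3L pair 45.4% of the higher and 52.3% of the lower genes moved alike. These percents count genes whose interval excludes 0 and so are lower at lower depth, while the median ratios were 0.76, 0.58 and 0.45 for the higher and -0.71, -0.60 and -0.68 for the lower genes in the sorted constitutive, conditional and Dnmt3L pairs. The gap of 23.5 points for the higher genes, between the limits of 10 and 30, therefore leaves open whether loss of Dnmt3A in Sertoli cells takes part. The cluster that holds 67.7% of the Sertoli-like cells of the knockout whole testis holds 3.87% of those of the sorted knockout library, which is consistent with a difference between the animals, their maturity or the preparation of the 2 samples.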

How the results depend on the processing

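Every alternative was planned before the data were seen except those named as added. Of 678 comparisons of named genes with an alternative, 662 kept direction and side of the threshold, 15 no longer passed and 1 reversed. That gene was Taok3 in differentiating cells with at most 10% mitochondrial UMIs, added, at 0.0346. These comparisons leave out named genes that an alternative could not test. The stricter limits on cells tested only 7 of 60, and stem-like clusters alone 16 of 20. The 23 alternatives for stage shares kept their sign, though the means under the stricter limits on cells were 1.53 against 2.77 for undifferentiated and -0.92 against -2.33 for differentiating cells, and no spermatocyte value exists under the stricter limits on cells, which left no spermatocytes in any library. Of 234 comparisons of single lists 177 kept their call, 37 lost and 19 gained one, and 1 reversed, the stem list of undifferentiated cells with stem-like clusters alone, added (adjusted p 0.0705 in camera).

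Of 160 comparisons of genes named within pairs 51 moved past their interval, as did 23 of 64 for cell types of the whole testis.

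Calls in all germ cells numbered 7272, and 3511 with equal cells per stage, 2633 without the pair block and 756 under the stricter limits on cells. Calls in undifferentiated cells numbered 5297, and 2758 with DESeq2, 1310 without the block, 15 under the stricter limits, and 1841 and 1495 with the added 10% mitochondrial limit and stem-like clusters alone. The added fit with stage genes left out of the clustering called 5266. Calls in differentiating cells numbered 2636, and 468 with DESeq2, 31 without the block, 448 under the stricter limits and 1445 with the added 10% limit. With each pair left out in turn they ranged from 3748 to 7315, 2431 to 4780 and 484 to 3860. Fewer libraries are fitted there, and stricter limits leave fewer cells and genes; the cause was not tested otherwise. Camera passed 10 lists in germ cells and 8 in undifferentiated cells, 0 in both with an estimated correlation, and 5 in undifferentiated cells without the block. Under the stricter limits germ cells were 1.83% of the knockout whole testis and 16.4% of the wild type, against 3.79% and 9.73%. The Rhox median of the whole-testis pair, 1.01, was 0.38 in undifferentiated cells alone and 0.49 with equal stages. The correlation of the Dnmt3L pair with the mean of the Dnmt3A pairs, 0.812, was 0.747 in undifferentiated cells. It was 0.719 with equal cells per stage, chosen after the data were seen. Correlations between the Dnmt3A pairs, 0.836 to 0.907, were lower there too, at 0.715 to 0.842 and 0.637 to 0.792. The Dnmt3L pair is the shallowest, and the knockout whole testis, with 147 germ cells, limits what can be read at low levels.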

Other observations

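Apoc1, an apolipoprotein gene, was higher in 5 somatic classes of the unsorted knockout testis, from 1 library per genotype. It was at 318 against 72.0 CPM in Leydig-like cells, 45.3 against 9.12 in mesenchyme, 537 against 13.5 in macrophages, 12.2 against 3.21 in peritubular cells and 3.72 against 1.20 in Sertoli-like cells, and had 2 against 0 UMIs in endothelial cells. Whether free RNA carries it between classes was not tested.

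Genes of the Sertoli-like cells moved alike in several pairs. Across 2926 genes that are not higher in germ cells, the Pearson correlation of the log2 ratios of the sorted constitutive pair was 0.831 with the whole-testis pair, 0.728 with the conditional pair and 0.523 with the Dnmt3L pair; genes are not independent replicates.

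The question whether genes of the X chromosome rise as a set in undifferentiated spermatogonia was put, with its limit, before that result was seen. Of 531 X-linked genes tested 157 rose and 74 fell, with a median of 0.10, and Rhox5, Gabrq and Magee2 led. Among all genes tested in this class 2700 of 13758 rose and 2597 fell. Camera gave an adjusted p of 0.707 with an estimated correlation and 0.378 with the preset one, both adjusted over all chromosomes. The unadjusted p of the X in camera were 0.0592 and 0.0189. With so few libraries the form with an estimated correlation can hardly pass any list, so it cannot decide the question. A rise of the X as a set is therefore neither shown nor excluded, and a p above the threshold does not show equality. In differentiating spermatogonia 159 of 518 rose and 12 fell, with an adjusted p of 1.83e-12 in camera with the preset correlation and adjusted p = 0.334 with an estimated correlation.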
